A study of Mus musculus with 6 samples.

How the data were processed

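ChIRP-seq (chromatin isolation by RNA purification) captures an RNA on crosslinked chromatin with tiled, biotinylated oligonucleotides and sequences the DNA that comes with it. The RNA here was Bloodlinc, also named alncRNA-EC7, a long noncoding RNA that arises from a super-enhancer. The cells were MEL cells, a mouse erythroleukaemia line that takes up an erythroid programme when treated with dimethyl sulfoxide (DMSO). Per the labels' protocols, cells were taken after 5 days in 2% DMSO, and libraries that do not keep the strand were sequenced on an Illumina instrument.

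The data were 6 libraries, each a condition of its own, plus 1 list for the whole series. They were a Bloodlinc pulldown whose label names no probe pool and does not say whether it was a capture of its own or combined reads (called the pulldown here), a pulldown with the even-numbered probes, a pulldown with the odd-numbered probes, a control without probes, a control with RNase, and an input. With 1 library per condition, no test across replicates exists. Every test below is over peak positions or peak scores, describes these libraries, and says nothing about the spread between cultures. The label of the input gives the same 5 days of DMSO as the others, whereas the names of its peaks carry the tag MELd0, so the day of that library is uncertain.

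Per the submitters' processing notes, reads were handled with Bowtie2 and bedtools against the mouse build mm9. Versions, the peak caller and its thresholds are not given in the sources used here. Each file is a deposited peak list without a header, and its only measurement is the authors' score for each peak, a whole number whose scale is not given in the sources used here. Scores were therefore used only to rank or compare peaks within a list. The lists give no read counts, so the depth is unknown. Intervals on shares of peaks are exact (Clopper-Pearson) 95% binomial intervals and cover only the counting of peaks.

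The peak names are numbered, and the numbers run to 27800 in the pulldown list, which holds 517 peaks, to 124782 in the even list, which holds 18114, and to 120836 in the odd list, which holds 20596. The input list holds 270 peaks with numbers up to 599. The no-probe list (124 peaks) and the RNase list (141 peaks) have no gap in their numbers. The pulldown, even, odd and input lists thus hold a part of the numbered peaks, and the rule of selection is not given in the sources used here. Whether peaks were left out of the no-probe and RNase lists before numbering or above the highest number cannot be told. The lowest score was 633 in the pulldown list, 350 in the even list, 357 in the odd list, 172 in the input, 20 in the no-probe list and 23 in the RNase list.

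Positions are given from 1, in mm9. Peaks counted as shared when they overlapped by at least 1 bp. For each pair of lists, the peaks of the first were placed at random 10000 times on their own chromosome, within the span of positions seen in any list, and a one-sided permutation p was the share of placements with as many overlaps. Its smallest possible value is 0.0001. Benjamini-Hochberg adjustment ran over the 12 comparisons of pulldown lists with controls, over the 2 comparisons of the pulldown with the probe pools and over the 3 comparisons among controls. Differences in median score and correlations used 100000 permutations, two-sided, with a smallest possible p of 1e-05. Shares per chromosome were tested with two-sided exact binomial tests and, over all 21 chromosomes, with a chi-square statistic against 100000 multinomial draws. Paired shares were tested with an exact McNemar test. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.

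The tests were checked on simulated data. Of 100 simulated pairs of unrelated lists with the sizes of the even and odd lists, 3% were called at 0.05. The lists were simulated with the uniform placement that the test uses, and tested with 199 placements. The 3% therefore does not cover peaks that favour certain positions. With 200 even peaks planted on odd peaks, all 10 simulated pairs were called and the mean excess found was 202. For the distribution of 268 regions over chromosomes, 3.5% of 200 simulated sets without an effect were called, and 36.5% of sets in which chromosome 15 had been doubled.

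Except for the additions named at the end of this paragraph, the main tests, the alternatives and the rule for naming regions were fixed before the data were examined. The rule names the 10 consensus regions with the highest score, the 5 highest consensus regions of chromosome 11 (from which Bloodlinc is transcribed), the 3 highest peaks of each control list, and any consensus region that meets a control peak. Alternatives were a reciprocal overlap of 50%, midpoints within 1 kb, the top 50% of peaks by score, local shifts of 10 to 100 kb in place of uniform placement, removal of chromosome 11, removal of peaks that meet a control peak, the other even and odd peaks as the background of the chromosome tests, and, for the share on chromosome 11, peaks within 100 kb counted once. Comparisons among controls, of the pulldown with each probe pool, and of score with sharing (including Fisher's exact test on the 100 highest-scoring peaks) were added after the data were seen, with their alternatives. So were 4 alternatives for the distribution over chromosomes, namely removal of chromosome 15, removal of chromosome Y, peaks within 100 kb counted once, and the product of even and odd densities, as well as the tests of the closing section.

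No gene annotation of mm9 was used here, and coordinates were not moved between builds. The 12 gene lists fixed in advance (among them globins, haem synthesis, red cell membrane and erythroid regulators, with other lineages as controls) and the planned annotation classes were therefore not analysed here, and regions are named by position alone. Gene numbers per chromosome came from a RefSeq table of GRCm38, of which no coordinate was used.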

Results

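Bloodlinc occupancy was mapped by ChIRP-seq in differentiated MEL cells, with 1 library each for a pulldown, the even and the odd probe pools, a no-probe control, an RNase control and the input. The deposited lists held 517 pulldown peaks, 18114 even peaks and 20596 odd peaks, with median widths of 565 bp, 436 bp and 442 bp. The no-probe control had 124 peaks, the RNase control 141 and the input 270, with median widths of 135 bp, 135 bp and 54 bp. Together the even peaks covered 8165 kb, the odd peaks 9416 kb and the pulldown peaks 303 kb. Because the pulldown, even and odd lists hold a selected part of their numbered peaks and the no-probe and RNase lists have no gap in their numbers, these counts do not measure enrichment on a common scale.

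The series gives 268 consensus regions, the intervals its authors retained above their thresholds. All 268 were identical, in position, name and score, to the 3-way intersections of the pulldown, even and odd lists, and they came from 267 of the 517 pulldown peaks. Their median width was 479 bp and they covered 130 kb. They lay on all 21 chromosomes with even and odd peaks, and 257 of the 268 (95.9%) lay outside chromosome 11, from which Bloodlinc is transcribed. Chromosome 11 makes up 4.62% of the span of positions seen in any list, so a share of this size outside it is near that given by span alone. No mm9 gene annotation was used here, so the genes at these regions are not named.

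The region with the highest pulldown score was on chromosome 11. Whether it is the Bloodlinc gene itself was not determined, as no mm9 annotation was used here. The pulldown peak spanned positions 102233495 to 102238439 (4945 bp) and had the highest score of its list, 4188, against 3081 for the next peak. The highest-scoring of the 18114 even peaks, with a score of 4732, lay inside it at 102235636 to 102237263. A further even peak at 102237409 to 102237943 ranked 51st with a score of 3911. A single odd peak of 2744 bp at 102235676 to 102238419 ranked 9th of 20596 with a score of 4756. The consensus therefore held a pair of intervals here, of 1588 bp and 535 bp. No input peak met the pulldown peak. The no-probe control had a peak of 181 bp at 102235119 to 102235299 with a score of 52, and the RNase control had a peak of 128 bp at 102234108 to 102234235 with a score of 50. Both lay inside the pulldown peak and outside the even and odd peaks, the nearer ending 336 bp before the first even peak.

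**Figure D1:**
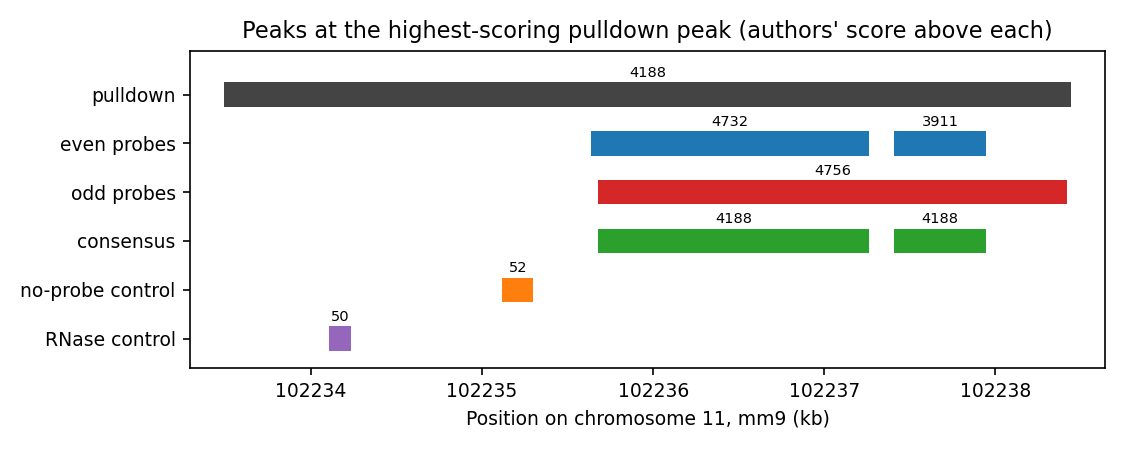
Peaks of each list at the highest-scoring pulldown peak, drawn to scale against position on chromosome 11 in mm9 (kb), with the authors' score above each bar. The even and odd peaks overlap in the right part of the 4945 bp pulldown peak, and the no-probe and RNase control peaks, with scores of 52 and 50, lie to their left.

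The other high-scoring consensus regions lay on 6 chromosomes. The region at 83663888 to 83664657 on chromosome 12 had the next highest pulldown score, 3081, and ranked 3rd among odd peaks with a score of 5196 but only 2135th among even peaks with a score of 2287. The region at 107637260 to 107637592 on chromosome 10 (pulldown score 1902) had the opposite order, with rank 42 in the even list and rank 13209 in the odd list. On chromosome 19, the region at 53894527 to 53894992 (pulldown score 1799) ranked 59th in the even list and 7102nd in the odd list. A further chromosome 19 region at 52780194 to 52780598 (pulldown score 1494) ranked 12787th in the even list and 1072nd in the odd list. On chromosome 15, the regions at 80520714 to 80521249 and at 44323060 to 44323662 had pulldown scores of 1427 and 1329 and ranked 38th and 87th among even peaks. The last of the 10 highest were at 152037572 to 152038161 on chromosome 5, with a pulldown score of 1307, and at 87450954 to 87451461 on chromosome 8, with a pulldown score of 1300. The pulldown peak with the 3rd highest score, 2840, at 56017383 to 56018110 on chromosome 16, met an odd peak and no even peak and was not in the consensus.

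The even and odd probe pools tile the same RNA with different oligonucleotides, and their overlap is the design's check on signal that is specific to a probe pool, as far as probes and DNA did not pass between the libraries. Of the even peaks, 2790 met an odd peak, which is 15.4% (95% interval 14.9% to 15.9%), and the same number of odd peaks, 13.5% (13.1% to 14.0%), met an even peak. Random placement gave a mean of 136 overlaps and at most 180, so the observed number was 20.5 times the random mean (one-sided permutation p = 0.0001, the smallest the test can give). With placement restricted to within 100 kb of each peak, the mean was 169, a ratio of 16.5, and the permutation p was again 0.0001. Control lists also passed this test. With local shifts their ratios were 82.2 (no-probe and RNase), 49.9 (no-probe and input) and 63.1 (RNase and input). With uniform placement the ratios were 12.7, 2232 and 5484 in the same order, so that of no-probe and RNase lay below the even-odd ratio of 20.5. The test therefore does not by itself tell sites of the RNA from positions that recur between libraries for other reasons. Most peaks of each pool had no partner: 84.4% of even peaks met neither an odd peak nor a pulldown peak, and 85.5% of odd peaks met neither an even peak nor a pulldown peak.

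Sharing depended on score in opposite ways in the even and odd lists. Among even peaks, 83.0% (81.2% to 84.7%) of the highest score decile met an odd peak, against 2.71% (2.01% to 3.57%) of the lowest. Among odd peaks, 4.23% (3.40% to 5.19%) of the highest decile met an even peak, against 14.5% (13.0% to 16.1%) of the lowest. Of the 100 highest-scoring even peaks 95 had an odd partner, and of the 100 highest-scoring odd peaks 5 had an even partner (Fisher's exact test over these peaks, two-sided, p = 1.26e-43). Shared even peaks had a median score of 2491 against 993 for unshared even peaks, a difference of 1498. Shared odd peaks had a median score of 1048.5 against 1165 for unshared odd peaks, so the difference was -116.5. Each difference had a two-sided permutation p of 1e-05, the smallest the test can give. The peaks within each list are positions in a single library, not replicates.

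**Figure D2:**
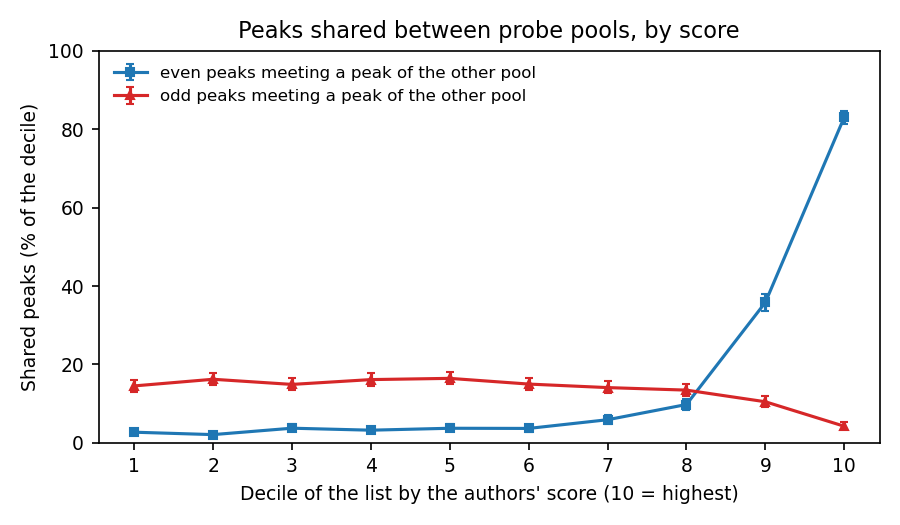
Share of even peaks that met an odd peak (blue squares) and of odd peaks that met an even peak (red triangles), in percent, by decile of the authors' score within each list; bars are exact 95% binomial intervals. The share reached 83.0% in the highest even decile and 4.23% in the highest odd decile.

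Across the 2790 pairs of shared peaks, even and odd scores were positively correlated, with Spearman's rho 0.488 and Pearson's r 0.399 (permutation p = 1e-05 for both, also after Benjamini-Hochberg adjustment over the pair). These are correlations across peaks, which are not independent replicates. Only 2 pairs were within the 100 highest scores of both lists, and both belonged to the chromosome 11 region described above. Within the 500 highest scores of both lists there were 5 pairs. Beyond the pair on chromosome 11, they were at 24135904 to 24136541 on chromosome 9, at 67552131 to 67552733 on chromosome 15 and at 107971752 to 107972346 on chromosome 1, with pulldown scores of 960, 816 and 1094. These 3 regions were singled out after their values were seen.

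**Figure D3:**
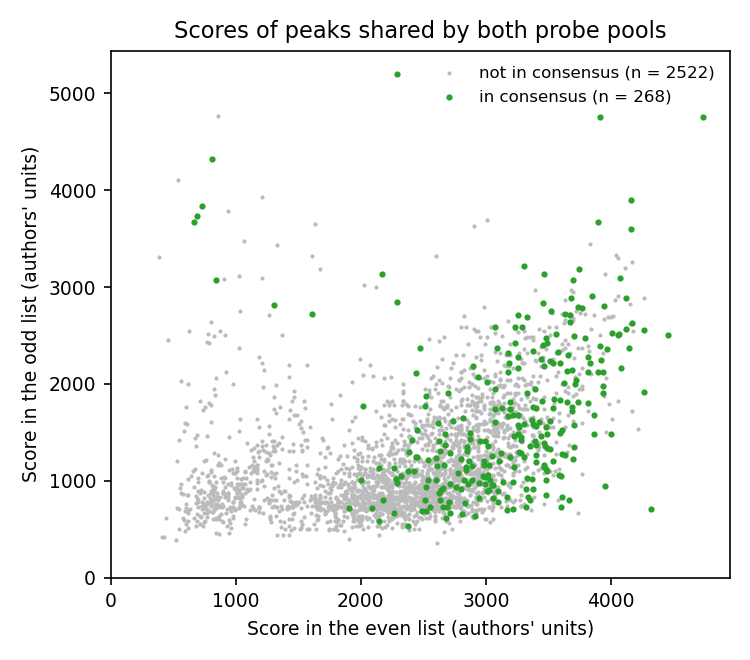
Authors' score in the odd list against the score in the even list for each of the 2790 peaks shared by both probe pools, on linear axes; green points are the 268 pairs in the consensus and grey points the other 2522. The even scores of consensus pairs have an interquartile range of 2805.5 to 3589.5, and the pairs of the chromosome 11 region lie at the upper right.

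The pulldown list was compared with each probe pool in the same way. Of its 517 peaks, 471 (91.1%, 88.3% to 93.4%) met an odd peak and 311 (60.2%, 55.8% to 64.4%) met an even peak, where random placement gave means of 4.55 and 4.05 (one-sided permutation, adjusted p = 0.0001 for both, the smallest the test can give). The pulldown met an odd peak alone 204 times and an even peak alone 44 times (exact McNemar test, two-sided, p = 8.28e-26). Only 2 pulldown peaks met neither pool. The sources used here do not say whether the pulldown was a separate capture or combined reads of the even and odd libraries. If reads were combined, these overlaps and the consensus would not compare separate libraries. The 204 odd peaks that met a pulldown peak and no even peak had a median score of 3622.5, against 1487 for the 267 odd peaks that met both. The 43 even peaks that met a pulldown peak and no odd peak had a median score of 2469, against 3256 for the 268 that met both. The consensus thus left out 204 pulldown peaks whose odd partners scored above most odd peaks in the consensus, since no even peak lay there.

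Consensus peaks had higher scores than the other peaks of each probe pool. Thresholds and intersection chose them, so the difference describes that selection and is no separate evidence of occupancy. Even peaks in the consensus had a median score of 3256 (interquartile range 2805.5 to 3589.5) against 1068.5 for other even peaks (794 to 1617). Odd peaks in the consensus had a median of 1487 (1048.5 to 2205) against 1145 (827 to 1760). Both differences had a two-sided permutation p of 1e-05, the smallest the test can give. Against only the 2522 other even peaks with an odd partner, whose median was 2403, the even difference was 853.

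The no-probe control, the RNase control and the input give the background of the method. None of the 268 consensus regions met a peak of the input, the no-probe or the RNase list. For the no-probe and RNase lists this followed from the intersection, since no even or odd peak met them, and is no separate evidence. For the input, the exact interval of the share reached up to 1.37%. Random placement gave at most 0.0198 such overlaps on average, so the test had no power to show a deficit (one-sided permutation p = 1). The even and odd lists met no peak of the no-probe or RNase control, and each met 1 input peak, against random means between 0.580 and 0.783. The pulldown list met 2 no-probe peaks against a random mean of 0.0230 (adjusted permutation p = 0.00480), namely in the chromosome 11 region and at 47392233 to 47392826 on chromosome 19. This overlap was lost when 50% of both peaks had to overlap. The pulldown list met 1 RNase peak, in the chromosome 11 region (adjusted permutation p = 0.128), and no input peak.

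A larger share of control peaks met another control list than met a pulldown, even or odd peak. These shares are not on a common scale, since the pulldown, even and odd lists hold a selected part of their numbered peaks. Relative to the random mean, the pulldown and no-probe lists had a ratio of 87.0, on 2 peaks. The ratios among controls were 12.7 (no-probe and RNase), 2232 (no-probe and input) and 5484 (RNase and input). Of the 124 no-probe peaks, 32 (25.8%, 18.4% to 34.4%) met an RNase peak and 25 (20.2%, 13.5% to 28.3%) met an input peak, and 17 of 141 RNase peaks (12.1%, 7.18% to 18.6%) met an input peak. The random means were 2.51, 0.0112 and 0.00310 (one-sided permutation, adjusted p = 0.0001 for each, the smallest the test can give). The shares were lower under a reciprocal overlap of 50%, at 23.4%, 6.45% and 4.96%, and without mitochondrial peaks and the first 1 Mb of each chromosome, at 16.3%, 9.18% and 5.41%, each with an adjusted permutation p of 0.0001. Of the 124 no-probe peaks, 15 met both other control lists, and 9 of the 15 lay within the first 1 Mb of called positions on chromosome 9. The highest no-probe peak, at 98506326 to 98507532 on chromosome 2 (score 771), had an RNase counterpart with a score of 544. The next, at 35112778 to 35113161 on chromosome 9 (score 617), had counterparts in the RNase list (511) and the input (733). The 3rd was mitochondrial, at 477 to 811, and the highest RNase peak was also mitochondrial, at 15955 to 16295 with a score of 780. The highest input peaks had a score of 868, at 70039156 to 70039291 on chromosome 4, at 3110005 to 3110091 on chromosome 12 and at 139917556 to 139917636 on chromosome X, and each met peaks of both other controls. None of these control peaks met a peak of the pulldown, even, odd or consensus lists.

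The share of consensus regions on chromosome 11 bears on whether occupancy gathered on the chromosome that encodes the RNA. Chromosome 11 held 11 of the 268 consensus regions, a share with an exact interval of 2.07% to 7.23%, against 4.62% expected from its share of the called span (exact binomial test, two-sided, p = 0.884). After the pair of intervals of the highest-scoring region, the highest were at 29711564 to 29712083 with a pulldown score of 1073, at 107133512 to 107133967 with 893 and at 82665924 to 82666501 with 878. A share of up to 7.23% is within the interval, so an excess of up to 1.56 times the expectation from span is not excluded. From the other even and odd peaks, 5.55% was expected (exact binomial test, two-sided, p = 0.351). On chromosome 11 the ratio to span was 1.21 for the even list, 1.19 for the odd list and 0.888 for the consensus.

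Consensus regions were not spread over the chromosomes in proportion to span (chi-square 74.9 over 21 chromosomes, permutation p = 7e-05). Chromosome 15 held 27 regions where 10.5 were expected, a ratio of 2.58 (1.73 to 3.67, adjusted exact binomial p = 0.000174). Chromosome 9 held 24 where 12.6 were expected, a ratio of 1.90 (1.24 to 2.77, adjusted exact binomial p = 0.0321). Chromosome 8 held 4 where 13.4 were expected and chromosome 7 held 6 where 15.6 were expected, ratios of 0.299 and 0.385 (adjusted exact binomial p = 0.0321 and 0.0446). The other 17 chromosomes did not pass the adjusted test, among them chromosome X with 8 regions against 16.8 expected (adjusted exact binomial p = 0.0955). The pulldown list, from which the consensus came, was itself uneven against span (chi-square 110, permutation p = 1e-05). Its ratios were 2.18 on chromosome 15, 1.72 on chromosome 9, 0.271 on chromosome 8 and 0.666 on chromosome 7. The even and odd lists had their own unevenness, with ratios of 1.33 and 1.21 on chromosome 9 and 0.513 and 0.552 on chromosome X, and with their highest densities, 10.6 even and 10.8 odd peaks per Mb, on chromosome 15. Against the chromosome counts of the even and odd peaks outside the consensus, the consensus still departed (chi-square 49.1, permutation p = 0.00326). Against the product of the even and odd densities, the expectation for overlaps of these lists by chance, it departed with chromosome Y (permutation p = 0.00565) and not without it (chi-square 23.9, permutation p = 0.198). On this background 20.5 regions were expected on chromosome 15, 19.7 on chromosome 9, 10.4 on chromosome 8 and 11.5 on chromosome 7. The unadjusted exact binomial p was 0.135, 0.293, 0.0387 and 0.128, so chromosomes 15, 9 and 7 did not stand out there. The value for chromosome 8 was not adjusted over the 21 chromosomes, unlike the tests against span, so it does not single out chromosome 8. This background was added after the data were seen, and it leaves out the pulldown list, the other member of the intersection. Most even-odd overlaps were also not of the chance kind it describes, with 2790 observed against a random mean of 136.

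**Figure D4:**
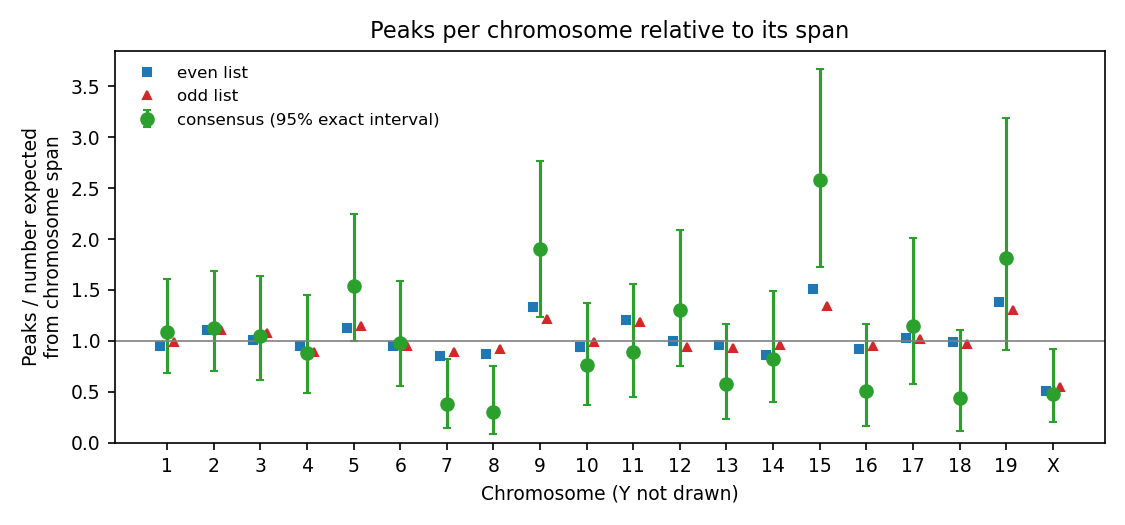
Number of peaks divided by the number expected from each chromosome's share of the called span, for consensus regions (green circles, with exact 95% binomial intervals), even peaks (blue squares) and odd peaks (red triangles); the line marks a ratio of 1 and chromosome Y is not drawn. Of the chromosomes drawn, chromosome 15 has the highest consensus ratio, 2.58, and chromosome 8 the lowest, 0.299.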

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

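The comparison of sharing with score and its tests were chosen after the result was seen; the test of list size and the test of the even threshold for the pulldown overlap were fixed before their results were computed. The odd pool differed from the even pool in 3 results. The share of pulldown peaks with a partner was 30.9 percentage points higher for the odd list than for the even list. The median score of shared minus unshared peaks was 1498 in the even list and -116.5 in the odd list, each with a two-sided permutation p of 1e-05, the smallest the test can give. The difference between these 2 median differences was not itself tested; among the 100 highest-scoring peaks, 95 even and 5 odd peaks had a partner in the other pool (Fisher's exact test, two-sided, p = 1.26e-43).

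The size of the odd list is argued against as the cause. With the odd list reduced to its 18114 highest scores, 88.4% (85.3% to 91.0%) of pulldown peaks still had an odd partner, and 90.0% (88.0% to 91.8%) of the 1000 highest even peaks did, whereas 3.20% of the 1000 highest odd peaks met an even peak. Loss of even partners under the even threshold stays open for the pulldown: only 0.965% (0.199% to 2.79%) of even peaks that met the pulldown were among the lowest 25% of even scores, but the 204 pulldown peaks with an odd partner alone have no even score, so this does not bear on them. Whether sites of the even pool were also captured, at a lower level, in the odd library stays open: 93.2% (92.2% to 94.1%) of shared peaks had the higher score percentile in the even list, but pairing the same percentiles at random already gave 86.7% to 89.6% over 10000 draws. The observed share lay above these draws, but most of it follows from the pattern itself, and the excess was not tested against the correlation of the paired scores. Transfer of probes or DNA between the libraries and a difference in probe specificity also remain open, and no biological explanation was tested because both pools target the same RNA.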

How the results depend on the processing

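Of 121 alternative values for 38 results, 112 kept the side of the threshold, or stayed within the spread. The same direction was required only where the main or the alternative value was past the threshold. Some overlaps with controls that moved between above and below the random mean are therefore counted among the 112. Many of the 112 had little room to change, so their number does not measure robustness. Among them are overlaps with controls that rest on few or no peaks. Others are the membership of the consensus in the lists it was intersected from, and the merging of touching peaks, which changed no count. Keeping the top 50% of each list by score lowered the number of peaks by construction, to 265 pulldown, 9057 even, 10388 odd, 135 input, 75 no-probe, 88 RNase and 135 consensus peaks. The overlap of the pulldown with the no-probe control fell to 0% under a reciprocal overlap of 50%, as the control peak on chromosome 11 spans 181 bp of a 4945 bp pulldown peak (the cause for the other peak was not tested), and held under the other alternatives. The chromosome distribution, tested against the product of even and odd densities, was past the threshold with chromosome Y (permutation p = 0.00565) and not without it (chi-square 23.9, permutation p = 0.198), since 1 region lay on Y where 0.0282 were expected. The test against the product was added after the data had been examined and before its own result was known, and Y was left out after that result was seen. Against span and against the other even and odd peaks it held without Y (permutation p = 1e-05 and 0.00566), and against span it held without chromosome 15 (permutation p = 0.00062), a removal chosen after the data had been seen. The even-odd overlap ranged from 12.5% to 16.5% of even peaks over its alternatives, each with a permutation p of 0.0001. No paired analysis was possible because each condition had 1 library, and for the same reason no replicate was left out. The gene lists and annotation classes, with their own settings, were not run, as no mm9 annotation was used here. The unknown depth and the selection of peaks in the lists limit each comparison with the controls.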

Other observations

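The tests of neighbouring regions (with draws from all shared peaks and with draws per chromosome), of the window around the highest-scoring region and of the product of densities were added after the data had been examined but before their own results were known; the overlap tests of the pulldown with the controls were fixed earlier, and the other tests in this part, among them the draws limited by score and the removal of Y, were chosen after the result was seen. Consensus regions lay near each other: 102 of the 267 pulldown peaks behind them had another within 1 Mb, against a mean of 60.7 in 10000 random draws from even peaks with an odd partner (permutation p = 0.0001, the smallest the test can give). With draws that kept the number per chromosome the mean was 67.2, and with draws limited to even scores of at least 2805.5 it was 71.2, each with a permutation p of 0.0001. The 14 groups of 3 or more regions included 5 regions at 121427073 to 122485731 on chromosome 5, 5 at 64795281 to 66608200 on chromosome 9, 4 at 101886857 to 102397210 on chromosome 3 and 4 at 79720763 to 80586708 on chromosome 15. In this order, the groups named held 18, 21, 18 and 12 even peaks and 19, 28, 16 and 16 odd peaks. The draws did not match the local density of all even and odd peaks, and matched chromosome and score only separately. The genes there and the local copy number were not analysed here.

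A hypothesis of occupancy spreading along chromosome 11 around the highest-scoring region was not borne out in both probe pools. The 2 Mb around it held 25 even peaks (88.1st percentile of 10000 random windows of the chromosome) and 33 odd peaks (96.8th percentile). The percentile for the even list was under the 95 set for both lists. The window also held 2 pulldown peaks (94.6th percentile) and 3 consensus regions (98.95th percentile against a random mean of 0.166), of which 1 pulldown peak and 2 consensus regions were those of the highest-scoring region itself.

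For the uneven spread of consensus regions over chromosomes, gene density is argued against as the whole cause, because the regions did not follow the numbers of protein-coding genes over the 20 chromosomes without Y (chi-square 85.1, permutation p = 1e-05, the smallest the test can give). Chromosome 7, with 13.6 genes per Mb, had 0.385 (0.142 to 0.827) of the regions expected from its span and chromosome 19, with 12.1, had 1.81 (0.912 to 3.19), and a partial role of gene density is not excluded (Spearman's rho 0.194, permutation p = 0.410; Pearson's r 0.128, permutation p = 0.595, and 0.418 without chromosomes 7 and 11). A chromosome-wide factor common to the libraries is a candidate explanation: over these 20 chromosomes, the density of even peaks without an odd partner went with that of odd peaks without an even partner (Spearman's rho 0.838 and Pearson's r 0.957, permutation p = 1e-05 for both, the smallest the test can give, and 4e-05 and 2e-05 adjusted over 4 relations), and r was 0.927 without chromosomes 15 and X. This does not tell DNA copy number from other factors common to both pools, and the relation of the consensus itself to the other peaks (rho 0.795) is largely set by its being an intersection of these lists. Whether the even and odd densities alone account for the consensus stays open, with a permutation p of 0.00565 on all chromosomes and 0.198 without Y, and neither copy number nor a biological difference between chromosomes was measured here.

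A peak of the no-probe control and a peak of the RNase control lay inside the highest-scoring pulldown peak on chromosome 11. Over all pulldown peaks, chance position is argued against for the 2 that met a no-probe peak, of which this is 1 (adjusted permutation p = 0.00480, and 0.00840 with local shifts), and is not excluded for the RNase peak (adjusted permutation p = 0.128, and 0.354 with local shifts). At this region alone, placement gave a permutation p of 0.00037 for a no-probe peak and 0.0003 for an RNase peak, computed after the overlap had been noticed. Carry-over of DNA from the pulldown cannot be told apart from other causes. Of the 20 strongest pulldown peaks 1 held a control peak, and it was this region, which had raised the question. Chromatin at this region that is recovered without probes was not tested.

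The 2 pulldown peaks that met neither probe pool were at 62252469 to 62253470 on chromosome 14 and at 47392233 to 47392826 on chromosome 19, and the latter held a no-probe control peak. Of the 515 other pulldown peaks, 1 held a control peak. Whether control peaks had been left out of the even and odd lists cannot be told from this, as the test (Fisher's exact, two-sided, p = 0.00773) was made after that peak had been seen and rests on 1 peak in each class.

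The RNase control had 16 mitochondrial peaks among 141 (11.3%, 6.63% to 17.8%), covering 7580 bp, and the no-probe control had 4 among 124 (3.23%, 0.886% to 8.05%), covering 1040 bp (Fisher's exact test over peaks, two-sided, p = 0.0179). The input, pulldown, even and odd lists had 0 mitochondrial peaks. In the input, 75 of 270 peaks (27.8%, 22.5% to 33.5%) lay on chromosome X and 51 (18.9%, 14.4% to 24.1%) on chromosome Y, which hold 6.28% and 0.104% of the called span.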
